A study of Homo sapiens with 96 samples.

How the data were processed

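RNA levels of the human promyelocytic leukaemia line HL-60 were measured in 96 libraries, which the labels place in 32 groups of 3. The groups are untreated cells, cells 3, 6, 12, 24, 48, 96 and 120 h after PMA (called macrophages in the labels), after DMSO with all-trans retinoic acid (neutrophils) or after vitamin D3 (monocytes), and monocytes of 120 h that were given PMA and collected at 123, 126, 132, 144 and 168 h (monocyte-derived macrophages). LPS was given for about 3 h to macrophages at 48 h and 120 h, to neutrophils and monocytes at 120 h and to monocyte-derived macrophages at 168 h. The authors deposited 1 table per library with FPKM values for the same 17222 Ensembl genes. STAR, Cufflinks and the genome build hg38 are named in the submitters' processing notes, without versions. The labels do not say which annotation was used, how many reads each library held, or whether the 3 libraries of a group came from separate cultures. Read depth is therefore unknown, and precision is judged only from the spread between libraries.

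No value in the files is 0. For 2271, 2291 and 2424 genes, at least 10 of the 32 libraries of replicate number 1, 2 and 3 share 1 lowest value, and in all 1375 genes where this holds for all 3 numbers, the value differs between the numbers. The deposited values therefore carry the trace of a per-gene adjustment or floor by replicate number that the labels do not state, and FPKM at this floor cannot be read as a measured level. Library totals ran from 202100 to 501360 FPKM (median 318118), library medians from 1.26 to 3.23 FPKM, and the 15 mitochondrially encoded genes held 6.5 to 57.2% of a library's total (median 23.0%). Gene symbols came from a current name table (16917 IDs), with names and hg38 coordinates from GENCODE v29 (17014 IDs, 11759 of them protein-coding).

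The following choices were made before the data were examined: the groups, the 20 comparisons, the main test, the 25 gene lists, the rule for which genes are named and the first set of alternatives. Genes with at least 1 FPKM in at least 3 libraries were kept (16097). Group means of log2(FPKM + 1) were fitted over all 96 libraries (64 residual degrees of freedom) in limma 3.58.1 under R 4.3.3 with trended empirical Bayes, without a replicate term (prior degrees of freedom 6.4 as the median over genes). A gene is called where the Benjamini-Hochberg adjusted p over all genes tested is under 0.05 and the log2 fold change is at least 1 in either direction. The median standard error of a log2 fold change was 0.29, and 0.41 for a difference between 2 responses. With a pseudocount of 1, fold changes of genes near 1 FPKM are pulled towards 0. Named genes are the 6 called genes with the most positive and the 6 with the most negative change whose libraries do not overlap between the groups (5 and 5 for differences between responses), up to 4 called members of each list, and 16 genes fixed in advance. Small RNAs and non-coding RNAs with systematic symbols (such as those starting with MIR, SNOR or LINC) were left out of the largest changes, while non-coding RNAs with other symbols stayed in, and genes with only an Ensembl ID are counted but not named. ELANE and TNF, both fixed in advance, were not analysed here.

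Gene lists were fixed from general knowledge: azurophil granule proteins, neutrophil maturation, monocyte genes, macrophage genes, vitamin D3 targets, retinoic acid targets, immediate early genes, NF-kB and cytokine genes, interferon-stimulated genes, cell cycle genes, ribosome biogenesis genes, myeloid transcription factors, the NADPH oxidase, lysosome genes, cholesterol synthesis, MHC class II, adhesion and cytoskeleton, glycolysis and hypoxia, the unfolded protein response, markers of erythroid, lymphoid, fibroblast and epithelial cells and of other granulocytes, mitochondrially encoded genes and heat shock genes. Lists were tested with limma camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 23 lists that had at least 3 genes tested. The MHC class II list had only CD74 and the erythroid list only HBA1 among the genes tested. Each list was tested again with the correlation estimated from the data. In the main fit this estimate used the residuals of all 96 libraries, so a library unlike its group enters it in every comparison. Members called were counted over all genes and adjusted over the list alone.

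Replicates 1 and 3 turned out to be far closer to each other than to replicate 2 in most groups, so a fit with replicates 1 and 3 averaged as 1 value was added after the data were seen (32 residual degrees of freedom). From that point a gene is said to have risen or fallen only where it was called in the main fit, in the averaged fit and after quantile normalization, and other genes are given as values. This stricter wording was chosen after the data were seen. Pairing by replicate number was checked by correlating the deviations from the group means of same-numbered libraries. Every pair was above 0.1 in 6 comparisons (DMSO with retinoic acid at 3 h, macrophages against monocytes, and LPS in 48 h macrophages, 120 h macrophages, monocytes and monocyte-derived macrophages), and replicate number as a block is given there where it moves a count by over 1.5 times. The pairing comes from the values and not from the labels.

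The alternatives were a pseudocount of 0.1, no expression filter, quantile normalization, scaling each library to the same total, replicate as a block, array weights, only the groups of a comparison, no fold minimum, 96 h in place of 120 h, an estimated correlation for the lists, and leaving out 1 library at a time. The same total was set above that of every deposited library, so the pseudocount of 1 weighed less in that alternative. Added after the data were seen were the averaged fit, the averaged fit without the second untreated 120 h neutrophil library (1 value is then left for that group, which is assumed to vary like the other groups), a common total over the genes that are not mitochondrial, 144 h in place of 168 h (with 24 h in place of 48 h macrophages), and a block in fits of only the groups compared. Library labels were permuted within each comparison over all 10 splits of 3 against 3, and over 100 of 200 splits for differences between responses. Correlations of fold changes are across genes and carry no p-value.

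The procedure was tested on simulated data with 200 changed genes among 16097. With independent libraries the main fit recovered 186 with 6 false calls (180 and 3 when averaged), and 3 of 3 changed lists were found with 0 of 20 others. When replicates 1 and 3 were near copies with a correlation of 0.9, it recovered 184 with 395 false calls, and 19.4% of unchanged genes had unadjusted p under 0.05, while the averaged fit recovered 139 with 7 false calls. In that setting the averaged fit found 28, 56, 96 and 98% of genes changed by 1.5, 2, 3 and 4 log2 units. Changed genes were drawn only from those with a mean log2 level above 2 in 120 h monocytes and a residual SD under 1. The recovered shares therefore do not cover lower or more variable genes. Simulated noise was independent between genes, so the list result cannot tell whether the preset correlation is high enough. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures. Results for a few single genes are not reported here. No sequence reads were used, and no other cell line or patient sample was available for comparison.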

Results

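HL-60 cells, a human promyelocytic leukaemia line, were taken towards macrophages with PMA, towards neutrophils with DMSO and all-trans retinoic acid, or towards monocytes with vitamin D3, and RNA was measured from 3 to 120 h. Monocytes of 120 h were then given PMA to make monocyte-derived macrophages, and LPS was added for about 3 h to 5 of the cell states. The 32 groups held 3 libraries each. FPKM values are means ± SD over 3 libraries, and log2 fold changes of FPKM + 1 are given ± standard error from limma. Counts of called genes refer to 16097 genes tested and need a Benjamini-Hochberg adjusted p under 0.05 with a log2 fold change of at least 1. All p-values measure only the spread between these libraries, since separate cultures are not stated.

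Replicates 1 and 3 were the closest pair in 31 of 32 groups. The SD of log2 differences between them had a median of 0.24 over groups, against 0.72 between replicates 1 and 2 and 0.72 between 2 and 3. The exception was the 12 h neutrophil group, where replicates 2 and 3 were closest at 0.27 and replicate 1 lay at 0.87 from replicate 3. In 120 h macrophages with LPS replicates 1 and 3 were the closest pair but lay 0.649 apart. All 3 libraries were close in monocytes at 6 h and monocyte-derived macrophages at 123, 126, 132 and 144 h. There replicates 1 and 2 lay at 0.307, 0.345, 0.369, 0.361 and 0.379, and replicates 1 and 3 at 0.213, 0.246, 0.249, 0.251 and 0.245. Averaging replicates 1 and 3 may not be enough in such groups. Because 3 values of which 2 are nearly alike carry the information of about 2, each total of called genes is followed by the total with replicates 1 and 3 averaged. Standard errors and adjusted p-values of genes and lists come from the main fit unless averaging is named. That fit counts all 3 libraries as separate, so these errors and p-values are likely too small. "Rose" and "fell" are used only for genes called in the main fit, in the averaged fit and after quantile normalization.

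**Figure D1:**
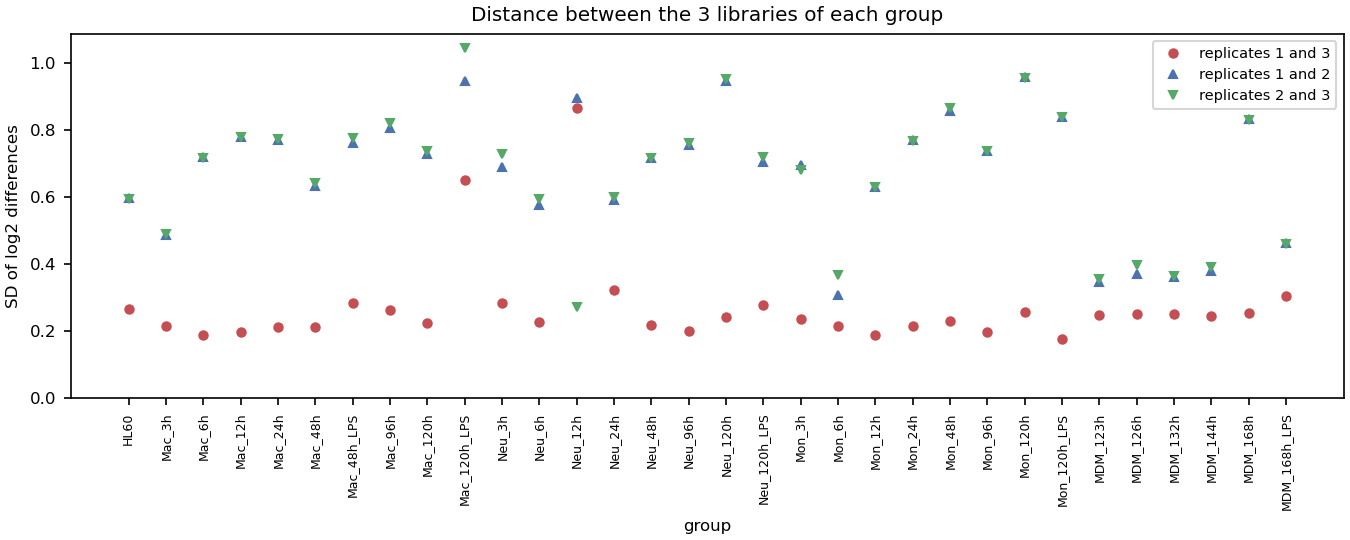
SD of the log2 differences between the libraries of each group, for replicates 1 and 3, 1 and 2, and 2 and 3, over genes of at least moderate level. A low point means that 2 libraries are nearly alike.

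The first question was what each inducer changed within 3 h. PMA raised the neutrophil attractant CXCL8 (ENSG00000169429, hg38 chromosome 4, 73740506 to 73743716) from 12.8 ± 14.6 to 1004 ± 83.0 FPKM (log2 fold change 6.96 ± 0.72; limma, Benjamini-Hochberg adjusted p = 1.3e-11). The growth-response transcription factors EGR1 and EGR2 rose by 6.01 ± 0.47 and 4.51 ± 0.49, the EGF receptor ligands AREG and HBEGF by 5.49 ± 0.57 and 3.21 ± 0.37, the activation marker CD69 by 4.51 ± 0.32 and the scavenger receptor OLR1 by 4.43 ± 0.47. GATA2, a factor of early blood progenitors, went up from 6.80 ± 0.536 to 65.9 ± 12.9 FPKM. The histone genes H2BC18, H2BC11 and H2BC21 fell by 2.91 ± 0.44, 2.85 ± 0.44 and 2.74 ± 0.35. Close relatives of these genes are hard to tell apart by reads.

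Among the fixed lists, 17 of 22 immediate early genes were called higher after 3 h of PMA and none lower (18 adjusted over the list alone, 14 when averaged), with JUNB up by 4.22 ± 0.34 and DUSP2 by 3.98 ± 0.50 (limma camera, Benjamini-Hochberg adjusted p = 7.4e-26, and adjusted p = 0.004 with an estimated correlation). NF-kB and cytokine genes had 17 of 27 members higher (18 adjusted over the list alone, 7 when averaged), including the feedback inhibitor TNFAIP3 (3.83 ± 0.52) and the subunit RELB (3.67 ± 0.47), with adjusted p = 0.239 with an estimated correlation. In the unfolded protein response list 10 of 16 were higher (10 adjusted over the list alone, 3 when averaged), with TRIB3 up by 2.67 ± 0.33, CHAC1 by 2.36 ± 0.38 and SESN2 by 1.73 ± 0.30, genes also known from amino acid shortage (adjusted p = 0.13 with an estimated correlation). Heat shock genes (3 of 8 higher, 1 when averaged), cholesterol synthesis (8 of 22 higher, 1 when averaged, HMGCS1 up by 1.84 ± 0.35) and mitochondrially encoded genes (9 of 13 higher, none when averaged) had adjusted p = 0.239, 0.294 and 0.282 with an estimated correlation. The mitochondrial share of the FPKM total was lower after PMA, 19.0 ± 1.20% against 24.8 ± 2.88% in HL-60. The mean totals were 327049 and 238006 FPKM. In all, 1567 genes were called higher and 126 lower (limma, Benjamini-Hochberg), 92.6% higher. The numbers were 308 and 50 with replicates averaged, and 474 and 422, or 52.9% higher, after quantile normalization. The median over all genes lay 0.27 above 0, so the split between higher and lower depended on the scaling.

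Within 3 h of DMSO with retinoic acid MYC, the growth-promoting transcription factor (ENSG00000136997, hg38 chromosome 8, 127735434 to 127741434), fell from 236 ± 12.2 to 13.4 ± 6.55 FPKM (log2 fold change -4.14 ± 0.43; limma, Benjamini-Hochberg adjusted p = 1.5e-11). MYB and NFE2, transcription factors of immature blood cells, fell by 2.26 ± 0.31 and 2.26 ± 0.25, the nucleotide receptor P2RY2 by 2.40 ± 0.24 and the glycosyltransferase B3GNT7 by 2.26 ± 0.21. SKIL, a repressor of TGF-beta signalling, rose by 2.26 ± 0.37, and HEXIM1, an inhibitor of transcription elongation, by 2.19 ± 0.22. IQCN rose by 2.44 ± 0.16, and HIC1, on the retinoic acid target list, from 0.222 ± 0.107 to 2.44 ± 0.591 FPKM. Of 20 myeloid transcription factors, 5 were called lower and 1 higher (6 adjusted over the list alone, 4 lower when averaged; limma camera, Benjamini-Hochberg adjusted p = 4.0e-08, and adjusted p = 0.00327 with an estimated correlation). The totals were 435 higher and 149 lower (74.5% higher), 112 and 32 when averaged, and 388 and 377 after quantile normalization (50.7% higher). With each library scaled to the same total 841 were higher and 325 lower (72.1% higher). With mitochondrial genes left out of that total the numbers were 502 and 246 (67.1% higher). With only these 6 libraries fitted and replicate number as a block, 0 genes passed in limma, with 3604 at unadjusted p under 0.05.

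Vitamin D3 had the fewest genes called at 3 h. The semaphorin SEMA6B (ENSG00000167680, hg38 chromosome 19, 4542593 to 4559808) rose from 2.40 ± 0.501 to 20.6 ± 0.444 FPKM (log2 fold change 2.68 ± 0.30; limma, Benjamini-Hochberg adjusted p = 4.4e-09), the myeloid receptor TREM1 by 2.40 ± 0.29 and the gluconeogenic enzyme FBP1 by 1.72 ± 0.23. Histone genes H3C12 and HIST1H3B fell by 2.14 ± 0.37 and 2.09 ± 0.32. CD14, the LPS co-receptor, stood at 11.4 ± 3.82 against 2.12 ± 2.15 FPKM, and CYP24A1, the enzyme that breaks down vitamin D, at 1.66 ± 0.488 against HL-60 values that recur unchanged in other groups and cannot be read as a measured level. These 2 genes were called in the main fit but not in the averaged one. On the vitamin D target list 6 of 16 genes were called higher (6 adjusted over the list alone, 3 when averaged; limma camera, Benjamini-Hochberg adjusted p = 2.8e-10, and adjusted p = 7.0e-05 with an estimated correlation). Over all genes 144 were higher and 29 lower (83.2% higher), 7 and 2 when averaged, and 116 and 87 after quantile normalization (57.1% higher). The total of 173 became 70 and 112 without HL-60 libraries 1 and 3, and 97 without vitamin D3 library 2, and with only these 6 libraries fitted SEMA6B alone passed.

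**Figure D2:**
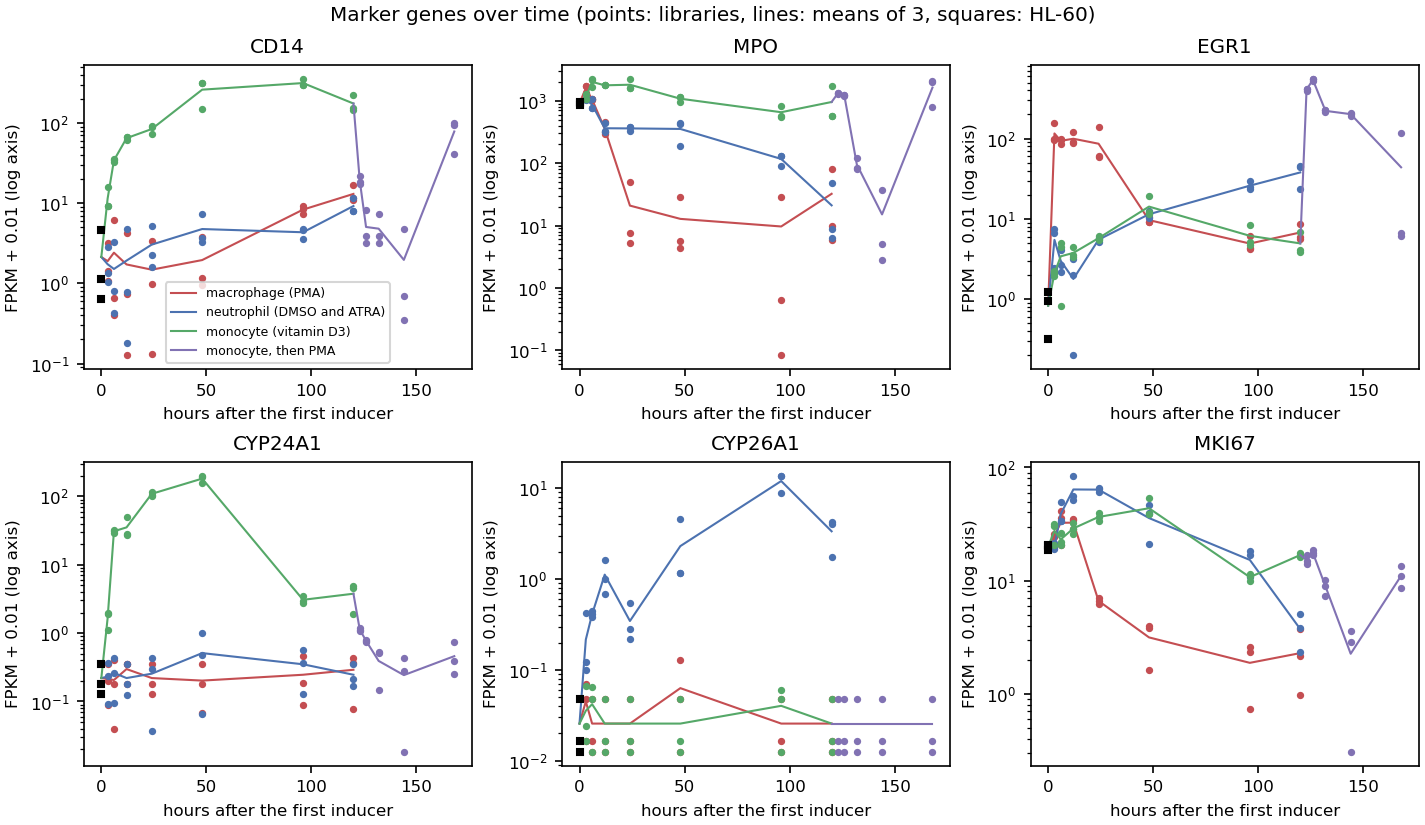
FPKM of CD14, MPO, EGR1, CYP24A1, CYP26A1 and MKI67 against hours after the first inducer, for the macrophage, neutrophil, monocyte and monocyte-derived macrophage series. Points are libraries, lines join means of 3, squares are untreated HL-60 cells, and the axis is logarithmic.

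The next question was what distinguished each cell state at 120 h from untreated cells. Macrophages held the cell fusion gene DCSTAMP (ENSG00000164935, hg38 chromosome 8, 104339087 to 104356689) at 481 ± 91.7 FPKM against 0.907 ± 0.425 (log2 fold change 7.99 ± 0.63; limma, Benjamini-Hochberg adjusted p = 7.4e-18). IL1RN, the interleukin-1 antagonist, rose by 7.64 ± 0.71, the retinoic acid carrier CRABP2 from 20.6 ± 10.1 to 3297 ± 186 FPKM, TSC22D1 by 7.59 ± 0.93 and the protease inhibitor A2M by 6.85 ± 0.38. The M-CSF receptor CSF1R rose from 1.07 ± 0.303 to 46.2 ± 2.42 FPKM. The granule enzyme MPO (ENSG00000005381, hg38 chromosome 17, 58269856 to 58280935) fell from 915 ± 44.3 to 32.3 ± 42.4 FPKM, MS4A3 by 4.96 ± 0.37, MYC by 4.87 ± 0.43 and MYB by 4.24 ± 0.31.

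In these macrophages 16 of 19 macrophage genes were called higher and none lower (14 when averaged), among them the chemokine CCL22 (6.66 ± 0.57), osteopontin SPP1 (6.48 ± 0.95), LGALS3 (5.17 ± 0.62) and APOE (5.06 ± 0.78) (limma camera, Benjamini-Hochberg adjusted p = 1.2e-07, and adjusted p = 0.0283 with an estimated correlation). Azurophil granule genes had 9 of 12 lower and 1 higher (adjusted p = 0.00639 with an estimated correlation), and cell cycle genes 27 of 30 lower and none higher (26 lower when averaged), with TYMS at -3.57 ± 0.50 and TOP2A at -3.47 ± 0.30 (adjusted p = 0.00639 with an estimated correlation). Ribosome biogenesis genes, FBL among them (-3.14 ± 0.26), had 16 of 24 lower and 1 higher (adjusted p = 0.0529 with an estimated correlation). Lysosome genes were higher in 21 of 28, including the cathepsins CTSD (5.26 ± 0.81) and CTSB (3.78 ± 0.30), and adhesion and cytoskeleton genes in 19 of 23 with 1 lower, including ANXA2 (6.72 ± 0.50) and CD9 (6.36 ± 0.61), both with adjusted p = 0.0885 with an estimated correlation. CD74, the only MHC class II gene tested, fell from 62.6 ± 1.53 to 15.4 ± 21.9 FPKM. The totals were 3969 higher and 1195 lower (76.9% higher), 3254 and 1087 when averaged, and 2292 and 2344 after quantile normalization (49.4% higher), with a median shift of 0.27. The share higher was 58.6% with each library scaled to the same total and 60.4% with mitochondrial genes left out of that total.

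In neutrophils at 120 h the genes of the NADPH oxidase, the enzyme of the oxidative burst, were higher as a list, with NCF1 at 146 ± 18.6 against 6.65 ± 1.02 FPKM and CYBB up by 3.33 ± 0.44 (limma camera, Benjamini-Hochberg adjusted p = 1.2e-05, and adjusted p = 0.00381 with an estimated correlation). The calcium-binding S100A9 rose from 110 ± 78.9 to 2684 ± 22.7 FPKM, properdin CFP by 5.38 ± 0.49, the adhesion molecule CEACAM1 by 5.68 ± 0.31, thrombospondin THBS1 by 6.76 ± 0.90 and the formyl peptide receptors FPR1 and FPR2 by 3.48 ± 0.29 and 3.16 ± 0.23. MPO fell by 5.91 ± 0.86, the granule protease CTSG by 5.59 ± 0.53, MYC by 4.13 ± 0.43 and CEBPA by 1.84 ± 0.27. With 96 h in place of 120 h CEBPA was at -0.89 and not called. Neutrophil maturation genes had 11 of 22 higher and 2 lower (9 and 2 when averaged; adjusted p = 0.0367 with an estimated correlation, but 0.0922 at the preset correlation with only these 6 libraries fitted), monocyte genes 11 of 16 higher (adjusted p = 0.007 with an estimated correlation), and azurophil genes 9 of 12 lower with 1 higher (adjusted p = 0.00381 with an estimated correlation).

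Retinoic acid targets were higher in 13 of 16 in the neutrophils (12 when averaged), with HIC1 at 25.5 ± 6.61 FPKM and DHRS3 up by 4.34 ± 0.44 (limma camera, Benjamini-Hochberg adjusted p = 7.4e-07, and adjusted p = 0.00381 with an estimated correlation). CYP26A1, which clears retinoic acid, rose from a floor value of 0.0157 to 3.36 ± 1.39 FPKM. Interferon-stimulated genes were higher in 12 of 19, with IFI6 up by 3.44 ± 0.30 and MX1 by 2.30 ± 0.24, though MX1 was at 0.99 and not called at 96 h (adjusted p = 0.00887 with an estimated correlation). Cell cycle genes were lower in 27 of 30 and ribosome biogenesis genes in 17 of 24 (adjusted p = 0.00381 and 0.00887 with an estimated correlation). NF-kB and cytokine genes had 24 of 27 called higher (21 when averaged; adjusted p = 0.24 with an estimated correlation), and here the second untreated library stood apart: CXCL8 was 83.4, 2160 and 79.5 FPKM and IL1B 1.87, 1190 and 0.278 in libraries 1, 2 and 3. Over all genes 3088 were higher and 1323 lower (70% higher), 2176 and 1139 when averaged, 2271 and 878 when averaged without that second library (which leaves that group 1 value and takes the spread from the other groups), and 2096 and 2097 after quantile normalization (50% higher), with a median shift of 0.16.

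Monocytes at 120 h had the fewest genes called against HL-60. CD14 (ENSG00000170458, hg38 chromosome 5, 140631728 to 140633701) rose from 2.12 ± 2.15 to 174 ± 42.2 FPKM (log2 fold change 6.00 ± 0.51; limma, Benjamini-Hochberg adjusted p = 4.2e-15). The lysosomal reductase IFI30 rose by 4.71 ± 0.81, the phospholipase PLA2G7 by 4.67 ± 0.31, CLEC4E by 3.75 ± 0.43 and S100A12 from 8.33 ± 0.0811 to 82.8 ± 0.971 FPKM. Of 16 monocyte genes 14 were called higher and none lower (9 when averaged; limma camera, Benjamini-Hochberg adjusted p = 6.7e-25, and adjusted p = 2.2e-08 with an estimated correlation). Vitamin D targets were higher in 10 of 16, including TREM1 (3.57 ± 0.29), SEMA6B (3.46 ± 0.30) and CYP24A1 (1.91 ± 0.26) (adjusted p = 4.4e-07 with an estimated correlation). Lysosome genes were higher in 12 of 28, with CTSZ up by 2.77 ± 0.25 (adjusted p = 0.024 with an estimated correlation). MPO was at 957 ± 667 FPKM, against 915 ± 44.3 in HL-60. In all 1041 genes were higher and 193 lower (84.4% higher), 515 and 83 when averaged, and 895 and 521 after quantile normalization (63.2% higher). At 96 h in place of 120 h, 2484 genes were called.

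Genes that differed from HL-60 at 120 h were counted backwards through the time course without a test. Of the 3969 genes higher in macrophages, 18.1% were already at least 1 log2 unit higher at 3 h, 36.8% at 6 h and 62.1% at 48 h. For the 3088 in neutrophils the shares were 7.9, 35.9 and 64.3%, and for the 1041 in monocytes 14, 25.3 and 47.7%. The macrophages' 1195 lower genes were down in 6.9% at 3 h and 67.1% at 24 h, the neutrophils' 1323 in 9.4% at 3 h and only 43.5% at 96 h. All these shares use the values as deposited, and mean FPKM totals differed between groups. The total was 238006 in HL-60, 327049, 242792 and 249734 in macrophages, neutrophils and monocytes at 3 h, and 307882 in neutrophils at 6 h. Part of the contrasts between shares can therefore follow library totals, which was not tested.

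Fold changes against HL-60 were compared across genes, with no p-value because genes are not independent. Neutrophils and monocytes had r = 0.66 (0.67 after quantile normalization), macrophages and neutrophils 0.56 (0.59) and macrophages and monocytes 0.44 (0.47). A shared control alone gave r = 0.5 in simulation, so covariances say more: 0.42, 0.67 and 0.33 against a simulated 0.13. Macrophages and neutrophils shared 1675 higher genes (761 if independent) and 708 lower (98), with 75 in opposite directions. Macrophages and monocytes shared 633 higher (257) and 120 lower (14), neutrophils and monocytes 787 (200) and 153 (16). The 3 HL-60 libraries were not divided between the comparisons, so part of each excess can come from the shared control.

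Direct comparisons at 120 h asked which genes separate the cell states. Against monocytes, macrophages held more DCSTAMP (7.98 ± 0.63; limma, Benjamini-Hochberg adjusted p = 9.6e-18), CRABP2 (7.39 ± 0.55), IL1RN (6.94 ± 0.71) and CCL22 (6.56 ± 0.57). They held less of the eosinophil granule protein PRG2 (-5.42 ± 0.52), MPO (-5.50 ± 0.86), S100A12 (-4.97 ± 0.62), the lectin FCN1 (-3.98 ± 0.25) and CD14 (-3.65 ± 0.51). Monocyte genes were lower in 11 of 16 and higher in 2 (adjusted p = 0.0021 with an estimated correlation), azurophil genes lower in 9 of 12 (0.00106 likewise) and cell cycle genes lower in 20 of 30 (0.0127 likewise). Macrophage genes were higher in 13 of 19 and lower in 2 (adjusted p = 0.148 with an estimated correlation). MAF, a macrophage transcription factor, stood at 5.43 ± 0.473 FPKM against values in monocytes that mostly recur unchanged in other groups and cannot be read as a measured level. Called were 3064 higher and 1192 lower (72% higher), and 1853 and 1935 after quantile normalization (48.9% higher), with 3289 in all when averaged and 2769 with only these libraries and replicate as a block. The share higher was 57% with each library scaled to the same total and 57.8% with mitochondrial genes left out of that total.

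Neutrophils held more CEACAM1 than monocytes (5.43 ± 0.31; limma, Benjamini-Hochberg adjusted p = 3.9e-24), more of the retinoid enzyme DHRS3 (4.88 ± 0.44), HIC1 (4.42 ± 0.24), NCF1 (3.40 ± 0.46) and PGLYRP1 (3.10 ± 0.27), and less CST7 (-5.80 ± 0.36), CTSG (-5.49 ± 0.53), PRG2 (-5.47 ± 0.52) and CD14 (-4.09 ± 0.51). Retinoic acid targets were higher in 11 of 16 and lower in 1 (adjusted p = 0.000605 with an estimated correlation), and interferon-stimulated genes higher in 12 of 19, with IFI6 at 24.0 ± 2.23 against 1.87 ± 0.494 FPKM (adjusted p = 0.00121 with an estimated correlation). NADPH oxidase genes were higher in 4 of 6 (5 adjusted over the list alone; adjusted p = 0.0319 with an estimated correlation). Azurophil genes were lower in 9 of 12, cell cycle genes in 21 of 30 and ribosome biogenesis genes in 10 of 24 (adjusted p = 8.2e-05, 0.00599 and 0.0461 with an estimated correlation). Of 2530 genes called 1537 were higher and 993 lower (60.8% higher), 638 and 580 when averaged, and 1039 and 1339 after quantile normalization (43.7% higher). Averaged and without the second neutrophil library, with 1 value left for neutrophils and the spread taken from other groups, the count was 1164, and it was 1375 at 96 h.

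Between macrophages and neutrophils, DCSTAMP (7.70 ± 0.63; limma, Benjamini-Hochberg adjusted p = 4.7e-17), A2M (6.93 ± 0.38), CD9 (6.50 ± 0.61) and the lipase LIPA (3.66 ± 0.30) were higher in macrophages. THBS1 (-6.54 ± 0.90), CEACAM1 (-6.51 ± 0.31), CFP (-6.36 ± 0.49), the eosinophil and basophil protein CLC (-5.65 ± 0.45) and NCF1 (-4.45 ± 0.46) were lower. Neutrophil maturation genes were lower in 10 of 22 and higher in 1, monocyte genes lower in 9 of 16 and higher in 1, and macrophage genes higher in 13 of 19 (adjusted p = 0.000643, 0.0407 and 0.0407 with an estimated correlation). Cholesterol synthesis was higher in 11 of 22 (adjusted p = 0.23 with an estimated correlation). The totals were 2356 higher and 1330 lower (63.9% higher), 1874 and 963 when averaged, 1769 and 1694 after quantile normalization (51.1% higher), and 2366 in all when averaged without the second neutrophil library (1 value left for neutrophils, the spread taken from other groups).

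**Figure D3:**
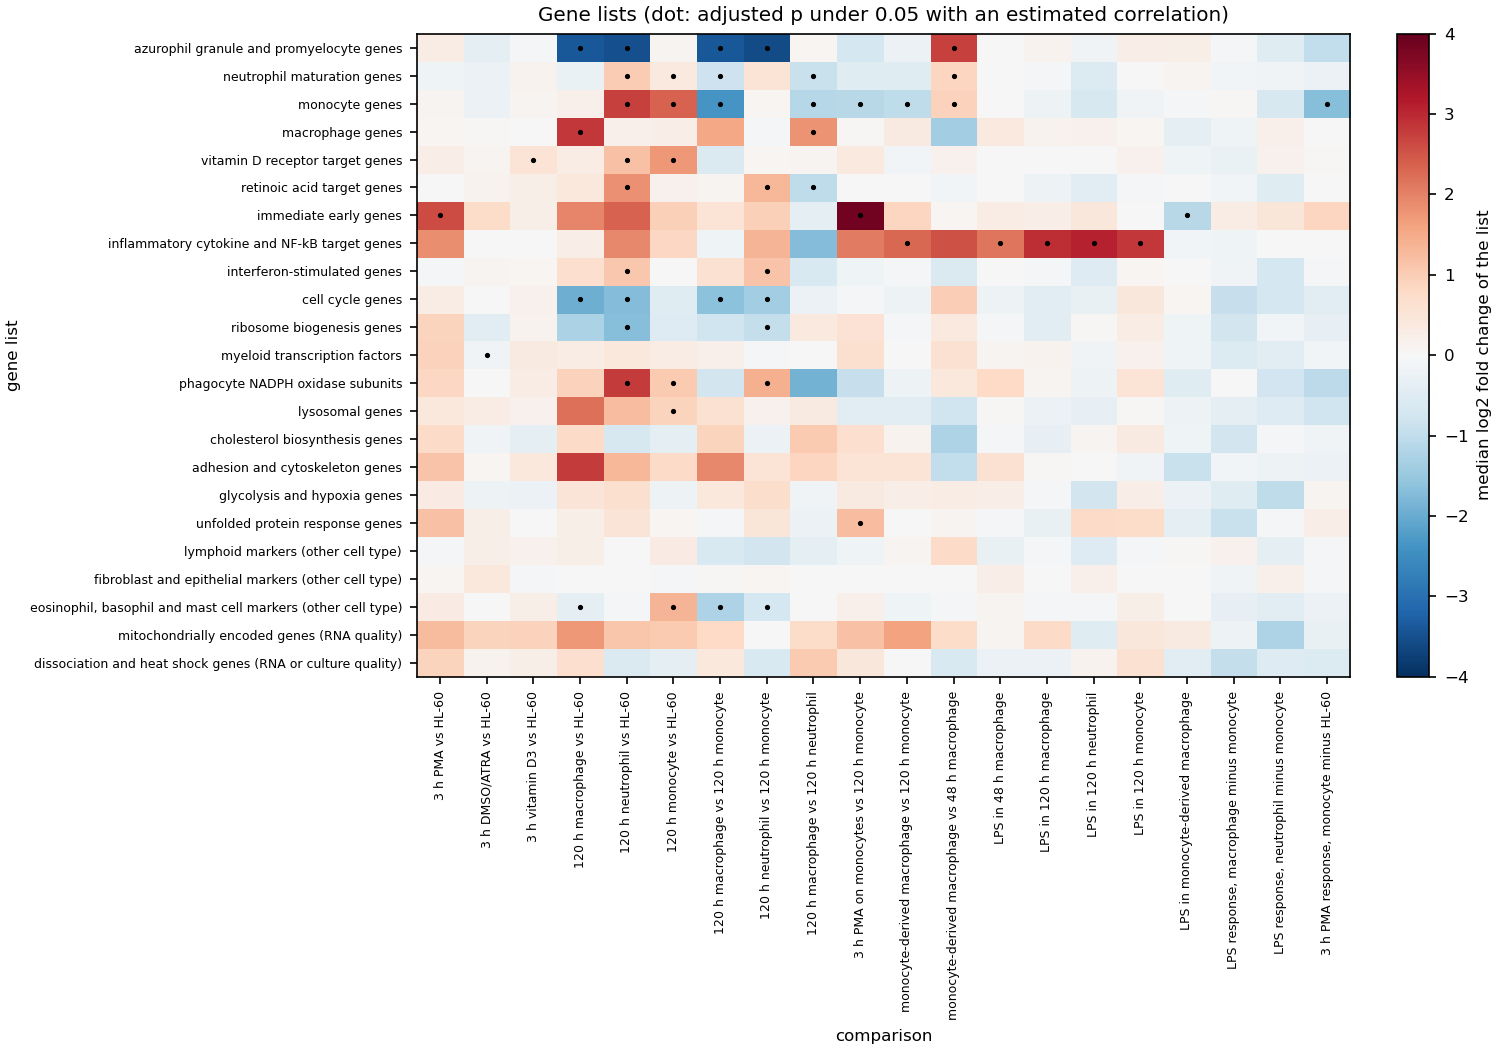
Median log2 fold change of 23 gene lists in the 20 comparisons. A dot marks a Benjamini-Hochberg adjusted p under 0.05 in limma camera with an estimated correlation.

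The second PMA step asked how monocytes respond to PMA. After 3 h, AREG rose from 0.717 ± 0.484 to 208 ± 6.86 FPKM (log2 fold change 6.97 ± 0.57; limma, Benjamini-Hochberg adjusted p = 4.5e-16), the haem-degrading enzyme HMOX1 from 1.75 ± 0.960 to 252 ± 14, EGR1 from 4.93 ± 1.73 to 408 ± 14.1, the nuclear receptor NR4A1 by 5.81 ± 0.40 and VGF by 5.74 ± 0.41. CD14 fell from 174 ± 42.2 to 19.1 ± 2.51 FPKM and the chemokine receptor CCR2 by 2.42 ± 0.26. Immediate early genes were called higher in 19 of 22 (17 when averaged; limma camera, Benjamini-Hochberg adjusted p = 1.2e-47, and adjusted p = 2.1e-05 with an estimated correlation). The unfolded protein response list was higher in 9 of 16, with CHAC1 up by 4.08 ± 0.38 and DDIT3 by 2.73 ± 0.40 (adjusted p = 0.0269 with an estimated correlation). Monocyte genes were lower in 8 of 16 and higher in 1 (10 adjusted over the list alone, 2 lower and 1 higher when averaged; adjusted p = 0.015 with an estimated correlation). Of the NF-kB and cytokine genes 17 of 27 were higher (19 adjusted over the list alone, 9 when averaged), with CXCL8 at 2443 ± 49.1 FPKM (adjusted p = 0.107 with an estimated correlation). In all 1085 genes were higher and 789 lower, and 446 and 207 when averaged. The split depended on the scaling, with 1036 and 902 after quantile normalization, 957 and 2224 with each library scaled to the same total (30.1% higher), and 925 and 1284 with mitochondrial genes left out of that total.

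Whether monocytes and HL-60 cells respond alike to 3 h of PMA was tested as a difference of the 2 responses. The proteinase MMP19 rose more in monocytes (difference 3.52 ± 0.49; limma, Benjamini-Hochberg adjusted p = 8.1e-07), reaching 178 ± 5.24 from 4.15 ± 2.83 FPKM, as did the vasoconstrictor EDN1 (3.20 ± 0.47), the phosphatase DUSP1 (3.02 ± 0.47) and NR4A3 (2.98 ± 0.44). CTSZ had a more negative response in monocytes (-2.70 ± 0.35). With a pseudocount of 0.1 the differences of MMP19 (1.39), DUSP1 (2.61) and NR4A3 (2.16) were no longer called. Monocyte genes had the more negative response in 7 of 16 (10 adjusted over the list alone, 0 when averaged in limma; adjusted p = 0.0142 with an estimated correlation), and immediate early genes the more positive one in 9 of 22 (11 adjusted over the list alone; adjusted p = 0.0523 with an estimated correlation). Most of the monocyte genes were called higher in 120 h monocytes than in HL-60, where low genes have little room to fall. CD14, for example, stood at 2.12 ± 2.15 FPKM in HL-60 and 1.88 ± 1.14 after PMA, against 174 ± 42.2 and 19.1 ± 2.51 in monocytes. The monocyte list result therefore cannot tell a different response from a different starting level. The 1092 genes called (155 more positive, 937 more negative, 14.2% positive) became 9 and 12 when averaged, and 426 and 347 after quantile normalization (55.1% positive), with a median shift of -0.28. With each library scaled to the same total 192 were more positive and 598 more negative (24.3% positive). With mitochondrial genes left out of that total the numbers were 331 and 467 (41.5% positive). The count of 1092 was 707 without HL-60 library 1, 666 and 718 without monocyte libraries 1 and 3, and 659 and 618 without libraries 1 and 3 of monocytes after PMA. Across genes the 2 responses had r = 0.45, with 508 genes higher in both (106 if independent), 39 lower in both (6) and 44 opposite.

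The libraries labelled as monocyte-derived macrophages of 168 h, which by the labels had 48 h of PMA, held more of the chemokine CCL20 than 120 h monocytes (507 ± 137 against 8.95 ± 4.61 FPKM, log2 fold change 5.77 ± 0.75; limma, Benjamini-Hochberg adjusted p = 3.7e-08). The transcription factor POU2F2 rose by 4.52 ± 0.48, the cytokine IL6 by 4.44 ± 0.50 and the signalling adaptor TRAF1 by 4.10 ± 0.52, while CCR2 fell by 2.30 ± 0.26 and CYP24A1 by 1.66 ± 0.26. NF-kB and cytokine genes were called higher in 22 of 27 (24 adjusted over the list alone, 7 when averaged; limma camera, Benjamini-Hochberg adjusted p = 1.5e-32, and adjusted p = 0.00546 with an estimated correlation), and monocyte genes lower in 7 of 16 and higher in 1 (9 adjusted over the list alone, 2 lower when averaged; adjusted p = 0.00546 with an estimated correlation). Libraries 1 and 3 did not show the PMA program: over 2023 genes raised in 48 h macrophages they lay at -0.16 log2 units relative to 120 h monocytes, against 0.63 in library 2 and 0.89 at 144 h. EGR1 was 6.68, 119 and 6.15 FPKM and MPO 2030, 799 and 2050 in libraries 1, 2 and 3, while MPO at 144 h was 15.1 ± 19.4. Mitochondrially encoded genes held 46.5, 29.5 and 46.0% of the FPKM total in these libraries, against 26.0 ± 4.38% in 120 h monocytes. Called were 441 higher and 451 lower (49.4% higher), 90 and 71 when averaged, and 344 and 1892 with each library scaled to the same total (15.4% higher). With only these 6 libraries fitted 8 genes passed, CCL20 and POU2F2 at adjusted p = 0.0446, but not IL6 (0.0609), TRAF1 (0.0515), CCR2 (0.0785) or CYP24A1 (0.124). The total of 892 became 489, 1677 and 502 without monocyte libraries 1, 2 and 3. With 144 h in place of 168 h it was 3527 (2077 higher, 1450 lower), or 2392 when averaged, and IL6 was no longer called (1.03).

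Against macrophages made from HL-60 with 48 h of PMA, monocyte-derived macrophages of 168 h held more MPO (7.20 ± 0.86; limma, Benjamini-Hochberg adjusted p = 1.9e-10), CXCL3 (6.49 ± 0.54), PRG2 (5.92 ± 0.52) and CD14 (4.77 ± 0.51), and less CRABP2 (-6.23 ± 0.55), A2M (-5.91 ± 0.38) and DCSTAMP (-5.71 ± 0.63). Azurophil genes were higher in 9 of 12, neutrophil maturation genes in 9 of 22 with 2 lower, and monocyte genes in 8 of 16 with 2 lower (adjusted p = 0.00164, 0.017 and 0.0435 with an estimated correlation). Macrophage genes were lower in 11 of 19 and higher in 1 (adjusted p = 0.315 with an estimated correlation). These values carry the same difference between the 168 h libraries as above, in PMA genes and in mitochondrial share. Called were 1408 higher and 2500 lower (36% higher), 992 and 1167 when averaged, and 1953 and 1869 after quantile normalization (51.1% higher), with a median shift of -0.14. The share higher was 30.5% with each library scaled to the same total and 41.9% with mitochondrial genes left out of that total. At 144 h against 24 h macrophages, 1779 were called (1332 higher, 447 lower), or 855 when averaged, MPO (-0.53), CD14 (0.15) and DCSTAMP (-0.16) were not called, CRABP2 was at -1.61 and not called when averaged (adjusted p = 0.22), and PRG2 was at -1.51 (adjusted p = 0.0312), or -1.15 and not called when averaged (adjusted p = 0.474).

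LPS was given to 5 cell states to ask how each responds to a bacterial signal. In 48 h macrophages the adaptor TRAF1 rose from 1.88 ± 0.142 to 72.6 ± 21.2 FPKM (log2 fold change 4.63 ± 0.52; limma, Benjamini-Hochberg adjusted p = 8.0e-10), the antioxidant enzyme SOD2 by 4.55 ± 0.62, MARCKS by 4.11 ± 0.64 and the cytokine subunit IL23A by 3.78 ± 0.61. NF-kB and cytokine genes were called higher in 19 of 27 (22 adjusted over the list alone, 6 when averaged; limma camera, Benjamini-Hochberg adjusted p = 1.2e-25, and adjusted p = 0.0404 with an estimated correlation, or 0.0811 when averaged). The totals were 378 higher and 223 lower, 65 and 5 when averaged, 388 and 296 after quantile normalization, 381 and 560 with each library scaled to the same total, and 324 and 439 with mitochondrial genes left out of that total. The sum of 601 became 376 without untreated library 3 and 273, 1246 and 255 without LPS libraries 1, 2 and 3. With only these 6 libraries and replicate as a block 0 passed in limma, with 2836 at unadjusted p under 0.05.

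In 120 h macrophages NFKBIA, the NF-kB inhibitor, rose from 15.4 ± 21.9 to 427 ± 67.3 FPKM and the chemokine CCL1 from 30.5 ± 15.7 to 1497 ± 127 (log2 fold changes 5.75 ± 0.96 and 5.68 ± 0.79; limma, Benjamini-Hochberg adjusted p = 4.5e-06 and 6.2e-08). IL23A rose by 5.60 ± 0.61, TRAF1 by 5.23 ± 0.52 and CXCL8 from 160 ± 17.4 to 1821 ± 28.1 FPKM. RASL11B fell by 3.00 ± 0.17, the growth factor VEGFA by 2.19 ± 0.29, MAF from 5.43 ± 0.473 to 0.582 ± 0.343 FPKM and the glycolysis regulator PFKFB4 by 2.03 ± 0.34. On the NF-kB and cytokine list 21 of 27 genes were higher (21 adjusted over the list alone, 16 when averaged; limma camera, Benjamini-Hochberg adjusted p = 2.5e-34, and adjusted p = 0.00785 with an estimated correlation). Of 1869 genes called 387 were higher and 1482 lower (20.7% higher), 188 and 604 when averaged, and 587 and 511 after quantile normalization (53.5% higher), with a median shift of -0.22. Other scalings kept most called genes lower. They gave 358 and 3724 with each library scaled to the same total (8.8% higher), and 341 and 1824 with mitochondrial genes left out of that total (15.8% higher). The libraries with LPS stood apart, with FPKM totals of 404571 ± 112949 against 320641 ± 27664 without LPS, an SD of log2 differences of 0.649 between replicates 1 and 3, and a mitochondrial share of 34.0 ± 3.62% against 25.5 ± 1.16% without LPS. VEGFA and PFKFB4 were not called with only these 6 libraries fitted (adjusted p = 0.0619 and 0.074). With only these 6 libraries and replicate as a block 0 passed in limma, with 3827 at unadjusted p under 0.05.

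LPS in 120 h neutrophils brought IL23A up by 4.45 ± 0.61 (limma, Benjamini-Hochberg adjusted p = 7.4e-08), the matrix-binding TNFAIP6 by 4.44 ± 0.58, IL1A by 4.36 ± 0.57 and the kinase PIM2 by 3.88 ± 0.50. The eosinophil chemokine receptor CCR3 fell from 22.9 ± 15.4 to 1.29 ± 0.182 FPKM, CEACAM1 by 2.41 ± 0.31, CSF1R by 2.06 ± 0.29 and CYP26A1 by 1.68 ± 0.17. IL1B stood at 1375 ± 39.8 FPKM with LPS and at 399 ± 689 without, since the second untreated library held 1190. NF-kB and cytokine genes were higher in 26 of 27 (26 adjusted over the list alone, 7 when averaged; limma camera, Benjamini-Hochberg adjusted p = 2.4e-35, and adjusted p = 0.00653 with an estimated correlation, or 0.0961 when averaged). Glycolysis and hypoxia genes were lower in 10 of 23 and higher in 2 (adjusted p = 0.519 with an estimated correlation). Over all genes 559 were higher and 1255 lower (30.8% higher), 56 and 125 when averaged, and 799 and 919 after quantile normalization (46.5% higher). The total of 1814 was 1042, 3180 and 1011 without untreated libraries 1, 2 and 3, and 1348 (418 higher, 930 lower) when averaged without library 2, a fit with 1 value left for untreated neutrophils that assumes they vary like the other groups and so is no test of the response on its own. With only these 6 libraries fitted 0 passed in limma, with 3638 at unadjusted p under 0.05.

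Monocytes of 120 h answered LPS with CCL20, up from 8.95 ± 4.61 to 584 ± 12.0 FPKM, and with the neutrophil attractant CXCL6, up from 0.660 ± 0.0657 to 59.9 ± 3.19 (log2 fold changes 6.01 ± 0.75 and 5.20 ± 0.22; limma, Benjamini-Hochberg adjusted p = 4.9e-09 and 3.1e-31). TNFAIP6 rose by 4.99 ± 0.58, MARCKS by 4.62 ± 0.64, SOD2 by 4.36 ± 0.62 and IL1A by 4.33 ± 0.57, while CCR2 fell by 2.00 ± 0.26. Nearly the whole NF-kB and cytokine list was higher, 25 of 27 genes (27 adjusted over the list alone, 14 when averaged; limma camera, Benjamini-Hochberg adjusted p = 5.6e-42, and adjusted p = 0.00199 with an estimated correlation). The totals were 574 higher and 125 lower (82.1% higher), 153 and 17 when averaged, and 374 and 252 after quantile normalization (59.7% higher). Without LPS libraries 1, 2 and 3 the sum of 699 was 426, 1490 and 419. LPS library 2 stood apart, with a mitochondrial share of 34.8% against 18.3 and 18.2% in LPS libraries 1 and 3. Its nearest library was the second 168 h monocyte-derived macrophage library with LPS (SD 0.47), while it lay 0.837 from LPS libraries 1 and 3. Fitted alone with replicate as a block, these libraries gave 0 calls in limma, with 3298 at unadjusted p under 0.05.

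In monocyte-derived macrophages few genes were called after LPS, and the untreated libraries already held LPS genes at a high level. The mean log2 level of the NF-kB and cytokine list was 5.35 ± 0.08 without LPS and 5.18 ± 0.03 with it, against 2.82 ± 0.30 in 120 h monocytes, and IL1B stood at 284 ± 42.0 and 281 ± 7.39 FPKM without and with LPS. Untreated libraries 1 and 3 also lacked the genes raised by PMA, as did the libraries with LPS. Over genes raised in 48 h macrophages these lay at -0.16 and -0.17 relative to 120 h monocytes, against 0.63 in untreated library 2. Mitochondrially encoded genes held 40.7% of the FPKM total without LPS and 52.5% with it. The response to LPS therefore cannot be judged from this comparison. EGR1 stood at 2.74 ± 1.66 FPKM with LPS and 44.0 ± 65.0 without, the mean without LPS resting on the second library. That library carried PMA genes, so lower EGR1 or immediate early genes with LPS cannot be told from a difference in the PMA program. None of 27 NF-kB and cytokine genes was called. Immediate early genes were lower in 3 of 22 (13 adjusted over the list alone, 0 when averaged in limma; limma camera, Benjamini-Hochberg adjusted p = 7.6e-21, and adjusted p = 0.0155 with an estimated correlation), their mean log2 level being 2.36, 4.83 and 2.39 in untreated libraries 1, 2 and 3 and 1.92, 1.97 and 2.00 with LPS. Called were 8 higher and 81 lower (9% higher), 1 when averaged, a gene without a symbol, 37 and 101 after quantile normalization (26.8% higher), and 84 and 67 with a common total over the genes that are not mitochondrial (55.6% higher), so the direction of the split depended on the scaling. The total of 89 became 312, 7 and 304 without untreated libraries 1, 2 and 3, and 9 and 15 without LPS libraries 1 and 3. With only these libraries and replicate as a block 0 passed in limma, with 2480 at unadjusted p under 0.05.

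**Figure D4:**
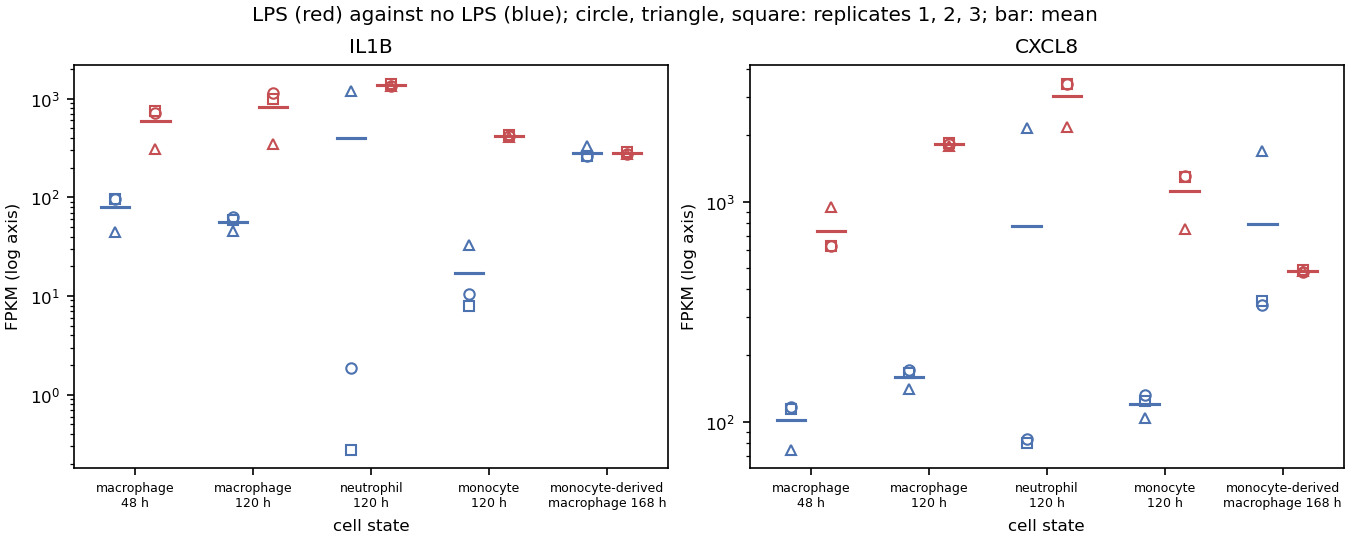
FPKM of IL1B and CXCL8 with LPS (red) and without (blue) in 5 cell states. Circles, triangles and squares are replicates 1, 2 and 3, and bars are means of 3.

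Whether macrophages and monocytes of 120 h respond differently to LPS was tested as a difference of responses. CXCL6 stood under 1 FPKM in macrophages with LPS, mostly at values that recur unchanged in other groups, and at 59.9 ± 3.19 in monocytes with LPS (difference -5.45 ± 0.31; limma, Benjamini-Hochberg adjusted p = 2.0e-23). The related chemokine CXCL5 (-4.36 ± 0.27) and IL6 (-4.09 ± 0.70) followed the same pattern, with IL6 at 0.116 ± 0.0475 and 23.1 ± 6.74 FPKM. VEGFA (-3.01 ± 0.41), MAF (-2.04 ± 0.14) and PFKFB3 (-2.07 ± 0.36) also had a more negative response in macrophages. MAF stood in untreated monocytes mostly at values that recur unchanged in other groups, so it had no measured level to lose there. Immediate early genes were more positive in 2 of 22 (limma camera, Benjamini-Hochberg adjusted p = 0.00659, and adjusted p = 0.677 with an estimated correlation). Of 2555 genes called 253 were more positive and 2302 more negative (9.9% positive), 27 and 145 when averaged, and 581 and 620 after quantile normalization (48.4% positive), with a median shift of -0.35. Other scalings kept most called genes more negative. They gave 261 and 2448 with each library scaled to the same total (9.6% positive), and 344 and 1603 with mitochondrial genes left out of that total (17.7% positive). Without monocyte LPS libraries 1 and 3 the count of 2555 was 1638 and 1653. Across genes the 2 responses had r = 0.10, with 111 genes higher in both (14 if independent), 28 lower in both (12) and 42 opposite.

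For neutrophils minus monocytes, CXCL6 again had the smaller response (-3.85 ± 0.31; limma, Benjamini-Hochberg adjusted p = 8.6e-16), with 2.79 ± 0.264 FPKM in neutrophils with LPS. ZMYND8 (-3.59 ± 0.43), the long RNA PELATON (-3.48 ± 0.52) and TREM1 (-2.81 ± 0.41) were also more negative, but with only the groups of this comparison fitted 23 genes passed and these 3 did not (adjusted p = 0.0921, 0.127 and 0.0749). Glycolysis and hypoxia genes were more negative in 6 of 23 (11 adjusted over the list alone; adjusted p = 0.78 with an estimated correlation). In all 90 genes were more positive and 594 more negative (13.2% positive), 2 and 19 when averaged, and 154 and 191 after quantile normalization (44.6% positive), with a median shift of -0.26. The count of 684 was 226, 2116 and 234 without untreated neutrophil libraries 1, 2 and 3, and 398, 1250 and 405 without those of monocytes. It was 382 and 383 without neutrophil LPS libraries 1 and 3, 372, 1113 and 383 without monocyte LPS libraries 1, 2 and 3, and 162 when averaged without the second untreated neutrophil library (1 value left there, the spread taken from other groups). Across genes r was 0.46, with 214 higher in both (20 if independent), 62 lower in both (10) and 9 opposite.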

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

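All tests of explanations in this part were chosen only after the results were seen.

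Replicates 1 and 3 were the closest pair in 31 of 32 groups, which argues against 3 cultures that each lie equally far from the others. The exact binomial p = 3.5e-14 takes the groups as independent, for a pair picked from these same data. Libraries of the same number may share handling, or the adjustment or floor by replicate number, so this p-value is likely too small. Whether that adjustment adds to the likeness was not tested. The median SD of log2 differences between replicates 1 and 3 was 0.24, against 0.72 between replicates 1 and 2, as 2 cultures handled together would give, but any small distance would meet that test, so it cannot tell. In the most abundant genes the spread between replicates 1 and 3 was 0.07, which a repeat measurement of 1 culture could give, and the test cannot tell that from 2 cultures handled together. The design gives no biological explanation, and none was tested.

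The second untreated neutrophil library of 120 h carried the genes that LPS raises. Over 153 genes raised by LPS in monocytes it lay 1.29 log2 units above the other 2 untreated libraries, against 1.56 for LPS libraries 1 and 3, and its nearest library was the second LPS library at an SD of 0.58. This is in line with LPS, or another inflammatory signal, having reached that culture, or with a library with LPS carrying this label. A swap with the second LPS library is argued against by that library's own shift of 1.18, and a general difference of replicate 2 by its highest shift of 0.27 in the 26 other groups without LPS (lowest -0.38, median 0.02). No biological explanation was given by the design, and none was tested.

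Libraries 1 and 3 of monocyte-derived macrophages at 168 h lacked the PMA program. Over 2023 genes raised in 48 h macrophages they lay at -0.16 relative to 120 h monocytes, against 0.89 at 144 h, 0.63 in the second 168 h library and -0.17 with LPS. Cells that received no PMA would give this, but these values restate the pattern and are no separate test of that explanation. Loss of the PMA response with time, the biological explanation, could not be decided. The second library lay 0.79 above the other 2, within the first limit set, 1 log2 unit. But the 144 h libraries lay only 1.05 above them, so a library that kept most of the response would also have met it. A replacement test, chosen after these values were known, found a gap of 0.81 between the libraries against at most 0.52 in 29 other groups. That gap was above each of the 29 but under the 2 times required. The 144 h distance of 1.05 would barely have passed that limit, so the replacement had the same fault. Over LPS genes the same libraries lay at 1.06, against 2.05 in monocytes with LPS, 0.44 at 144 h, 0.93 in the second library and 1.23 with LPS, so whether they could be monocytes that received LPS cannot be told. By nearest library, the second library of monocytes with LPS lay closest to the second 168 h library with LPS (SD 0.47) and next to 168 h library 3 (0.54), ahead of its own group (0.837), while 168 h library 2 lay closest to the second library of 144 h (0.42) and libraries 1 and 3 closest to each other (0.25), which leaves this open. CD14 was 98.1, 41.1 and 94.7 FPKM in libraries 1, 2 and 3, against 1.95 ± 2.48 at 144 h.

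A difference between 2 cell states in the same response was called for 2555 genes (172 with replicates averaged) in the LPS response of macrophages minus monocytes, 684 (21) in that of neutrophils minus monocytes and 1092 (21) in the 3 h PMA response of monocytes minus HL-60 (limma, Benjamini-Hochberg). For macrophages minus monocytes CXCL6 (-5.45), CXCL5 (-4.36), the mitochondrial enzyme PDHB (-4.61, adjusted p = 3.9e-07) and CYP24A1 (1.78, adjusted p = 0.000298) were flagged. For CYP24A1 the macrophage side rested on library 2 (0.444, 4.39 and 0.561 FPKM with LPS in libraries 1, 2 and 3, against 0.422, 0.067 and 0.353 without), and monocytes stood at 1.45 ± 0.609 with LPS and 3.76 ± 1.62 without. PDHB stood at 11.7 ± 8.39 FPKM in macrophages with LPS and 73.5 ± 25.4 without. In neutrophils minus monocytes CXCL6 (-3.85), ZMYND8 (-3.59) and PELATON (-3.48) were flagged, but ZMYND8 and PELATON were not called with only the groups of this comparison fitted. The PMA responses differed in MMP19 (3.52, but 1.39 and not called with a pseudocount of 0.1), EDN1 (3.20) and HSPE1P18 (-3.91), the last a pseudogene that reads of its parent gene can reach.

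When library labels were exchanged between the 2 groups of a comparison, the 10 possible splits were too few for a share under 0.05. The real split gave the most calls in each of the 17 comparisons of 2 groups (1 of 10). Genes called in the real and the best other split were 1693 and 5 for PMA at 3 h, 584 and 15 for DMSO with retinoic acid, 173 and 19 for vitamin D3, and, against HL-60 at 120 h, 5164 and 1034 in macrophages, 4411 and 1257 in neutrophils and 1234 and 70 in monocytes. They were 4256 and 1208 for macrophages against monocytes, 2530 and 1657 for neutrophils against monocytes, 3686 and 1248 for macrophages against neutrophils, 1874 and 612 for PMA on monocytes, 892 and 811 for monocyte-derived macrophages against monocytes, and 3908 and 2369 against 48 h macrophages. For LPS they were 601 and 195 in 48 h macrophages, 1869 and 488 in 120 h macrophages, 1814 and 1699 in neutrophils, 699 and 562 in monocytes and 89 and 9 in monocyte-derived macrophages. For the differences between responses, 1 of 100 splits, the real one, reached 2555 (highest other 1942) and 1 of 100 reached 1092 (337), but 16 of 100 reached 684 (2353), so the neutrophil minus monocyte count could come from the structure of the libraries alone.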

How the results depend on the processing

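The 144 h and averaged fits, the averaged fit without a neutrophil library, the common total without mitochondrial genes and the block in only the groups compared were chosen only after results were seen. Over all alternatives, 3155 values of named genes kept their call or lack of one, and their direction where called. Of the others 86 lost the call, 2 gained it and 8 reversed with a call in at least 1 of the 2 fits. A change of sign in a gene called in neither fit was not counted as reversed. Genes said to have risen or fallen had been chosen for a call in the main, averaged and quantile fits. Leaving out the fold minimum could not remove a call. Part of the values that kept their call was therefore fixed in advance and is no evidence of stability. IL1B in 120 h neutrophils against HL-60 was -1.54 with array weights and between -2.41 (without the second neutrophil library) and 2.52 (without library 3) when 1 library was left out. With 144 h in place of 168 h, MPO against monocytes was -6.43 (-6.19 when averaged), and against macrophages MPO was -0.53 (-0.50) and PRG2 -1.51 (-1.15). Depth is unknown, so no limit from depth can be given, and the cause of the shifts below was not tested unless their own construction gives it, as with fewer libraries or genes. No filter on low values kept all 21 counts within 1.5 times.

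Replicate number as a block in the fit of all libraries moved no count by over 1.5 times (1681 for PMA at 3 h and 169 list calls, for example). With every group holding each replicate number once, an adjustment by replicate number before deposit would leave such a block little to remove, so this says little about stability. In fits of only the groups compared, the block left 2769 genes for macrophages against monocytes, and 0 (limma) for DMSO with retinoic acid and for LPS in both macrophage ages, monocytes and monocyte-derived macrophages, where 3604, 2836, 3827, 3298 and 2480 had unadjusted p under 0.05. Without a block such fits left 585 for monocytes, 1041 for neutrophils against monocytes, 309 for DMSO with retinoic acid, 1 for vitamin D3 and 8 for monocyte-derived macrophages against monocytes. For LPS they left 97 and 380 in 48 h and 120 h macrophages, 0 in neutrophils (limma, 3638 at unadjusted p under 0.05), 181 in monocytes and 1 in monocyte-derived macrophages, and for differences between responses 605, 23 and 1761.

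Replicates averaged gave 358, 144 and 9 for the 3 inducers at 3 h, 598 for monocytes, 1218 for neutrophils against monocytes, 653 for PMA on monocytes, 161 and 2159 for monocyte-derived macrophages against monocytes and macrophages, 70, 792, 181, 170 and 1 for LPS (48 h and 120 h macrophages, neutrophils, monocytes, monocyte-derived macrophages, in this order throughout), and 172, 21 and 21 for differences between responses. Also without the second neutrophil library, which leaves untreated 120 h neutrophils 1 value that is assumed to vary like the other groups, 1164, 2366 and 162 were called for neutrophils against monocytes, macrophages against neutrophils, and the LPS response of neutrophils minus monocytes. With 144 h, 3527 and 1779 were called against monocytes and macrophages (2392 and 855 averaged). With 96 h, 2484 were called for monocytes and 1375 for neutrophils against monocytes.

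Quantile normalization gave 896 for PMA at 3 h, 1098 and 138 for LPS in 120 h and monocyte-derived macrophages, and 1201 and 345 for the differences of LPS responses. Scaling to the same total gave 1166 and 289 for DMSO with retinoic acid and vitamin D3, 1898 for monocytes, 3181 for PMA on monocytes, 2236 for monocyte-derived macrophages against monocytes, 941, 4082 and 2739 for LPS in 48 h and 120 h macrophages and neutrophils, and 317 for neutrophils minus monocytes. Without mitochondrial genes in the total the values were 900 for PMA at 3 h, 151 for LPS in monocyte-derived macrophages and 317 for neutrophils minus monocytes. A pseudocount of 0.1 gave 964 and 289 for DMSO with retinoic acid and vitamin D3, and 2972 and 2852 for LPS in 120 h macrophages and neutrophils.

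Array weights gave 953 and 641 for DMSO with retinoic acid and vitamin D3, 4145 for neutrophils against monocytes, 2883 for PMA on monocytes, 2244 for monocyte-derived macrophages against monocytes, 1861, 3834, 1735 and 306 for LPS in 48 h macrophages, neutrophils, monocytes and monocyte-derived macrophages, and 4979, 4751 and 3604 for differences between responses. Without a fold minimum there were 3040 and 1008 for PMA and DMSO with retinoic acid at 3 h, 6725 and 1877 for neutrophils and monocytes, 6501, 4398 and 5830 for macrophages against monocytes, neutrophils against monocytes and macrophages against neutrophils, 3145 for PMA on monocytes, 1393 and 6149 for monocyte-derived macrophages against monocytes and macrophages, and 1065, 3571, 3259 and 1085 for LPS in 48 h and 120 h macrophages, neutrophils and monocytes. Of 460 list tests 159 passed, and 52 with an estimated correlation (29 up, 23 down).

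Leaving out 1 library gave 99 counts within 1.5 times, 9 above and 30 below. The lowest and highest were 1373 and 1907 for PMA, 449 and 611 for DMSO with retinoic acid and 70 and 170 for vitamin D3 at 3 h. Macrophages, neutrophils and monocytes had 4924 and 5578, 4019 and 5069, and 967 and 1361. Macrophages against monocytes had 4001 and 4712, neutrophils against monocytes 2126 and 3333, macrophages against neutrophils 3565 and 3979, PMA on monocytes 1492 and 2536, and monocyte-derived macrophages 489 and 1677 against monocytes and 3294 and 4725 against macrophages. LPS had 255 and 1246, 1699 and 2303, 1011 and 3180, 419 and 1490, and 7 and 312. The differences between responses had 1638 and 3415, 226 and 2116, and 618 and 1539.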

Other observations

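No explanation was tested in this part, and the time courses below are values without a test. In the vitamin D3 series CD14, the LPS co-receptor, stood at 83.7 ± 10.2 FPKM at 24 h, 259 ± 94.8 at 48 h and 313 ± 32.8 at 96 h. CYP24A1, which breaks down vitamin D, was at its highest at 48 h (182 ± 23.7 FPKM) and at 3.06 ± 0.384 at 96 h. CYP26A1, which clears retinoic acid, had 12.0 ± 2.74 FPKM in neutrophils at 96 h. CEBPE, a factor of late granulocyte development, was at 124 ± 11.9 FPKM in neutrophils at 24 h and 65.3 ± 21.5 at 120 h, against 26.9 ± 3.96 in HL-60. EGR1 after PMA on monocytes was at 408 ± 14.1 FPKM at 3 h and 542 ± 17.5 at 6 h. The proliferation marker MKI67 stood at 63.7 ± 2.96 FPKM in neutrophils at 24 h, 20.0 ± 1.17 in HL-60 and 3.71 ± 1.34 in neutrophils at 120 h, and the mean log2 level of 30 cell cycle genes was 4.69 ± 0.11, 3.61 ± 0.22 and 1.80 ± 0.03 in the same groups. It was 2.05 ± 0.02 in macrophages at 24 h. Cholesterol synthesis genes had a mean of 4.12 ± 0.22 in monocytes at 48 h, 2.89 ± 0.18 in HL-60 and 2.90 ± 0.08 in neutrophils at 24 h.

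Markers of other cell types were present in part. In the list of other granulocytes 5 of 8 genes were called higher in 120 h monocytes than in HL-60, among them the eosinophil peroxidase EPX (13.5 ± 11.2 against 3.78 ± 0.930 FPKM) and the histamine-forming enzyme HDC (limma camera, Benjamini-Hochberg adjusted p = 2.3e-05, and adjusted p = 0.000286 with an estimated correlation). CLC, an eosinophil and basophil protein, was at 99.2 ± 19.1 FPKM in neutrophils of 120 h, and PRG2 was at its highest, 872 ± 36.5, in monocyte-derived macrophages with LPS. In HL-60 CLC was at 2.99 ± 1.29 and PRG2 already at 181 ± 9.6 FPKM. Of 4 lymphoid genes tested 2 were higher in monocyte-derived macrophages than in 48 h macrophages, with NKG7, a cytotoxic granule gene, at 20.2 ± 8.01 against 0.853 ± 0.681 FPKM (adjusted p = 0.0123, and adjusted p = 0.0623 with an estimated correlation), and no lymphoid test passed in the other 19 comparisons. NKG7 was already at 14.9 ± 1.25 FPKM in untreated HL-60, so its difference here is mostly a low level in 48 h macrophages. Libraries 1 and 3 of these monocyte-derived macrophages also lacked the PMA program. None of 9 fibroblast and epithelial genes was called in any comparison over all genes in limma (2 of 9 adjusted over the list alone for LPS in 48 h macrophages), and COL1A2 had the highest group mean, 12.7 ± 11.5 FPKM in monocytes at 6 h. HBA1, the only erythroid gene tested, had its highest mean in 48 h macrophages with LPS, 1.19 ± 1.03 FPKM. Mitochondrially encoded genes held 24.8 ± 2.88% of the FPKM total in HL-60, 40.7 ± 9.65% in monocyte-derived macrophages at 168 h and 52.5 ± 5.73% in these with LPS.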
